A study of Mus musculus with 6 samples.

How the data were processed

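The 6 samples were 3 DMSO and 3 TSA samples of mouse cells differentiated from embryonic stem cells, each hybridised to 1 single-colour (Cy3) Agilent array with 4 arrays per slide. Per the file headers, the deposited values of each array are intensity values from Agilent Feature Extraction (version 10.7 in the submitters' notes), with a processed signal that the software had background-subtracted and detrended within the array but not scaled between arrays. The deposited series table holds log2 values made by the authors; its normalization is not stated, its 6 columns share a maximum of 19.1, have medians of 8.17 to 8.21, and correlate at 0.995 with log2 of the processed signal. The processed signal was analysed and the authors' table served as an alternative. The dose of TSA is not given in the labels.

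Control spots and spots with an outlier flag (57 to 84 per array) were left out, log2 of the processed signal was taken, the 75th percentile of each array was subtracted, and spots of 1 probe were averaged. Of 41174 probes, the 28160 (68.4%) well above background on at least 3 of the 6 arrays, whatever their treatment, were tested. Probes were named through the symbols and RefSeq identifiers of the reference table: 27479 had 1 gene, 0 had several, and 13695 had no named gene and entered only the counts by probe. The arrays name 18749 genes, of which 14527 were tested, each by its tested probe with the highest mean over all arrays; 36.9% of these genes had more than 1 tested probe, and 0 changed genes had a probe called in the other direction. Nanog and Hdac1 had no named probe and were not analysed here. The array annotation and the reference table follow different genome builds, so no positions are given. Gene spans for 1 test came from the reference table.

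Treatment was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05; gene values carry the adjusted p of their probe, and errors are moderated standard errors. The p-values measure the spread among samples labelled as independent experiments. The labels name no block, so treatment was the only term. The replicate number is also the slide number, and the deviations of a DMSO and a TSA array of the same slide from their group means correlated at 0.484, 0.614 and 0.585, against -0.568 to 0.0916 for arrays of different slides, so the numbers pair the samples and values with the slide as a block are given where they change a call. Gene lists (37, with at least 5 tested genes) were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg over the 37 lists, and with an estimated correlation and fry as alternatives; fry asks whether the genes of a list move 1 way on balance. No list was called with an estimated correlation, where the lowest adjusted p was 0.693, and fry called 1. A loss with an estimated correlation need not come from correlation between genes. The mitosis list lost its call there though its estimate of 0.0040 was below the preset 0.01. Camera sets a list against the other tested genes, and the median difference over all tested genes was 0.08, so its direction is not against 0. The deviation of slide 2 is the median over a list of an array's level minus the mean of the other 2 arrays of its group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

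The 37 lists, the tests, the filter and the rule for named genes were fixed before the data were examined, while the lists to describe gene by gene were picked with their values known. The rule names the 10 largest rises and the 10 largest falls among genes past the threshold, in the same direction on all 3 slides, and above background and not saturated on all 6 arrays. It also names the 5 largest bounds among genes above background on all arrays of 1 treatment and on none of the other, a fixed set of key lineage and response genes, up to 4 members of each described list with the smallest adjusted p, and the deacetylase genes. It passes over genes known only by a clone or predicted-gene symbol, and not every gene it names is printed; the values of 2 of them are not reported here. A bound sets the mean of the TSA arrays against the mean over the DMSO arrays of the lowest signal called well above background, or of the gene's own signal where that was higher. Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization and median centring of the processed signal, the authors' table, 2 other filters, the slide block, an intensity trend with robust moderation, outlier spots kept, each array left out, each slide alone, and for lists the mean over a gene's probes; slide 2 left out, array weights, and array weights with the slide block were added later. The normexp alternative had been planned on mean spot signals, which the files do not give, and was run on median spot signals. The steps were tested on simulated data with 28160 probes and 3 against 3 arrays, drawn independently for each probe and with no slide effect. Of probes changed by 1, 2, 3 and 4 on the log2 scale, 2%, 50%, 68% and 84% were recovered, with 6 false calls. In these data 0 lists without a shift were called. That cannot test list calls among correlated genes, and the measured lists had estimated correlations such as 0.90 for definitive endoderm.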

Results

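Gene expression was measured in mouse cells that had been differentiated from embryonic stem cells in N2B27, a serum-free medium in which such cells tend toward neural fates. The samples are labelled as day 3 cells treated for 24 h either with the solvent DMSO or with trichostatin A (TSA), an inhibitor of histone deacetylases. Each treatment had 3 samples from independent experiments, and total RNA was hybridised to 6 single-colour Agilent arrays on 3 slides. Every slide held the DMSO sample of an experiment at position 3 and its TSA sample at position 4, so position and treatment cannot be told apart. The 75th percentile of the processed signal was 632, 653 and 924 intensity units on DMSO arrays 1, 2 and 3, and 671, 310 and 884 on TSA arrays 1, 2 and 3. Between 61.1% and 72.3% of the 43379 spots on an array lay well above background, and 0 were saturated. TSA replicate 2 was the dimmest array by its 75th percentile, and its correlation with the other TSA arrays was 0.931 and 0.939, against 0.984 to 0.990 for the other pairs within a group. The added control RNAs, relative to the 75th percentile, were 1.39 higher on the log2 scale on TSA replicate 2 than on the DMSO array of its slide, against 0.06 and 0.16 on the other slides. With 3 arrays per group, the number of arrays limits the precision of every value.

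The comparison of TSA with DMSO addresses what deacetylase activity does to gene expression as these cells choose between neural fates and the Nodal-dependent mesendoderm fates that give rise to mesoderm and endoderm. In TSA, 197 of 14527 tested genes rose and 8 fell. The largest rises among genes detected on all 6 arrays included Zscan4c and Tcstv1, genes of the early cleavage embryo, Usp17la, which encodes a deubiquitinating enzyme, and Esx1, a homeobox gene of placenta and testis. Tesc, for a calcium-binding protein, Tbx21, a transcription factor of T helper cells, and Spink2, a protease inhibitor of sperm, rose as well. Among the genes that fell were Cxcl12, a secreted chemokine, Ptn, the growth factor pleiotrophin, and Igfbp5, a binding protein of insulin-like growth factors. Of the risen genes, 15 were above background on 0 DMSO arrays and 141 on all 3. With those 15 set at their lower bound, the rises had a median of 1.94 and a range of 0.86 to 4.81 on the log2 scale. All 197 were higher in TSA on each of the 3 slides, which genes chosen by a test on the same arrays would nearly have to be.

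Differences are given as TSA minus DMSO on the log2 scale, with the standard error from limma and 3 arrays per group. That fit has no slide term, so its errors also hold level differences between experiments. Zscan4c rose by 3.62 ± 0.49 (12.3-fold, adjusted p = 0.0373), Usp17la by 3.59 ± 0.30 (adjusted p = 0.0208), Esx1 by 3.52 ± 0.36 (11.5-fold, adjusted p = 0.0246) and Tcstv1 by 3.47 ± 0.37 (adjusted p = 0.0246). Tesc rose by 3.40 ± 0.30 (adjusted p = 0.0208), Tbx21 by 3.21 ± 0.34 (adjusted p = 0.0246) and Spink2 by 3.01 ± 0.26 (adjusted p = 0.0208). Nrgn, a calmodulin-binding protein of synapses, rose by 2.90 ± 0.39 (adjusted p = 0.0373), Sphk1, a sphingosine kinase, by 2.85 ± 0.35 (adjusted p = 0.0305) and Paqr5, a progestin receptor of the cell membrane, by 2.81 ± 0.24 (adjusted p = 0.0208). Zscan4c, Usp17la and Tcstv1 belong to families of near-identical genes, so their probes may also bind relatives. Cxcl12 fell by 2.35 ± 0.29 (5.08-fold higher in DMSO, adjusted p = 0.0314), Ptn fell by 1.91 ± 0.21 (adjusted p = 0.0264) and Igfbp5 fell by 1.66 ± 0.25 (adjusted p = 0.0452). Tmem80 fell by 1.51 ± 0.20 (adjusted p = 0.0363), Tceal7 fell by 1.25 ± 0.19 (adjusted p = 0.0438), and Kbtbd11 fell by 1.26 ± 0.20 (adjusted p = 0.0489), while 2 further probes of Kbtbd11 gave -0.67 and 1.09 and did not pass. The other 2 fallen genes, 4933421O10Rik and Gm11627, carry only clone or predicted-gene symbols and fell by 2.0 and by 1.71.

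Some genes were above background on all 3 TSA arrays and on 0 DMSO arrays, and their folds are lower bounds against the background of the DMSO arrays. Pramel39, of a gene family expressed in germ cells and early embryos, was at least 19.3-fold higher in TSA (adjusted p = 0.0208). Cd52, a surface glycoprotein of lymphocytes, was at least 8.28-fold higher (adjusted p = 0.0239) and Tcstv3, a relative of Tcstv1, at least 5.88-fold higher (adjusted p = 0.0208). Degs2, a sphingolipid enzyme, was at least 5.66-fold higher (adjusted p = 0.0246) and Nobox, an oocyte homeobox gene, at least 4.45-fold higher (adjusted p = 0.0314). In all, 13 named genes had such a bound toward TSA and 0 had one toward DMSO.

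**Figure D1:**
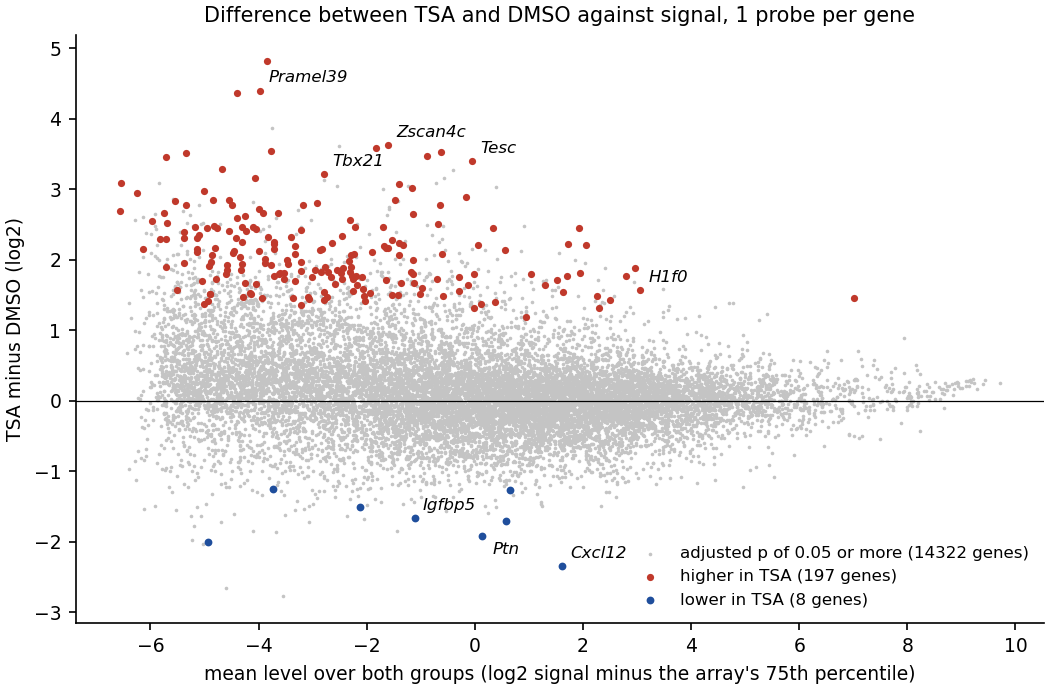
Each point is 1 of the 14527 tested genes, with the mean level over both groups (log2 signal minus the array's 75th percentile) on the x axis and the fitted TSA minus DMSO difference (log2) on the y axis. The 197 genes that rose (red) lie mostly at low mean levels, and the 8 that fell (blue) lie between -2.35 and -1.25.

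By probe, 259 of 28160 were higher in TSA and 10 were lower (limma, adjusted p under 0.05), all of them at least 2-fold as fitted. With the slide as a block, 618 probes were higher and 41 lower, which includes 264 of the probes called without it, and 465 genes rose and 21 fell. Leaving out TSA replicate 2 gave 571 higher and 54 lower probes. Leaving out any 1 of DMSO replicates 1, 2 and 3 and TSA replicates 1 and 3 gave 0 calls, with 2006 to 3327 probes at an unadjusted p under 0.05 and a lowest adjusted p between 0.0582 and 0.161.

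Genes of the primitive streak and of the mesoderm that comes from it had higher mean levels in TSA as groups, while no single member passed over all genes. Of 21 tested mesendoderm and primitive streak genes, 18 had a higher mean in TSA, with a list median of 0.80, and 0 rose or fell, over all genes or adjusted over the list alone. Nodal, the secreted signal that induces mesendoderm, gave 1.15 ± 0.33 (adjusted p = 0.211, and 0.0601 with the slide as a block), and the streak gene T gave 1.57 ± 0.71 (adjusted p = 0.470, and 0.0665 with the block). Mixl1, a homeobox gene of the streak, gave 2.59 ± 0.94 (adjusted p = 0.332) and Evx1, another, 2.70 ± 1.06 (adjusted p = 0.384). With the slide as a block both of these passed (adjusted p = 0.0310 and 0.0329), and 6 members of the list rose. On slides 1, 2 and 3 Mixl1 differed by 2.83, 2.67 and 2.27, and T by 2.26, 1.05 and 1.39. Snai1, a repressor of epithelial genes, gave 1.76 ± 0.58 (adjusted p = 0.281), Eomes 0.34 ± 0.69 (adjusted p = 0.853) and Gsc, an organizer gene, 0.60 ± 1.00 (adjusted p = 0.820). Of 23 tested mesoderm genes, 20 had a higher mean in TSA, with a median of 0.84, and 0 rose or fell, over all genes or adjusted over the list alone. Msgn1 gave 3.87 ± 1.10 (adjusted p = 0.204, and 0.0310 with the block), Tbx6 3.03 ± 1.21 (adjusted p = 0.392, and 0.0363 with the block) and Tcf15 1.32 ± 0.31 (adjusted p = 0.128, and 0.0490 with the block); all 3 are transcription factor genes of paraxial mesoderm. With the block, 6 members of the mesoderm list rose.

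Against the other tested genes, the mesendoderm list was higher in TSA by camera (adjusted p = 0.0341, and 9.81e-05 with the slide as a block) and so was the mesoderm list (adjusted p = 0.0267, and 1.60e-04 with the block). With an estimated correlation the adjusted p was 0.878 for both. The list medians on slides 1, 2 and 3 were 0.98, 1.05 and 0.54 for mesendoderm and 1.26, 0.99 and 0.55 for mesoderm. The second experiment stood apart in these genes in both treatments: the median mesendoderm gene was 2.0 higher on TSA replicate 2 than on the other TSA arrays and 1.75 higher on DMSO replicate 2 than on the other DMSO arrays, against 0.37 and 0.06 over all tested genes. For mesoderm genes these deviations were 1.16 and 0.55. The mesendoderm call ended without DMSO replicate 1 (0.75, adjusted p = 0.240), TSA replicate 2 (0.43, adjusted p = 0.243) or DMSO replicate 3 (0.81, adjusted p = 0.101). The mesoderm call ended without DMSO replicate 1 (0.45, adjusted p = 0.431), TSA replicate 2 (0.68, adjusted p = 0.109) or TSA replicate 3 (0.83, adjusted p = 0.137), and with quantile normalization (0.79, adjusted p = 0.0569), normexp background correction (0.22, adjusted p = 0.0551) or no filter (0.72, adjusted p = 0.0737). No filter also ended the mesendoderm call (adjusted p = 0.0710). Normexp lowered the mesendoderm median to 0.47 (adjusted p = 0.0405). Leaving out TSA replicate 2 alone keeps DMSO replicate 2, which was also high in these genes. With both arrays of slide 2 left out, camera still called mesendoderm (0.65, adjusted p = 2.36e-04) and mesoderm (0.77, adjusted p = 0.00893).

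**Figure D2:**
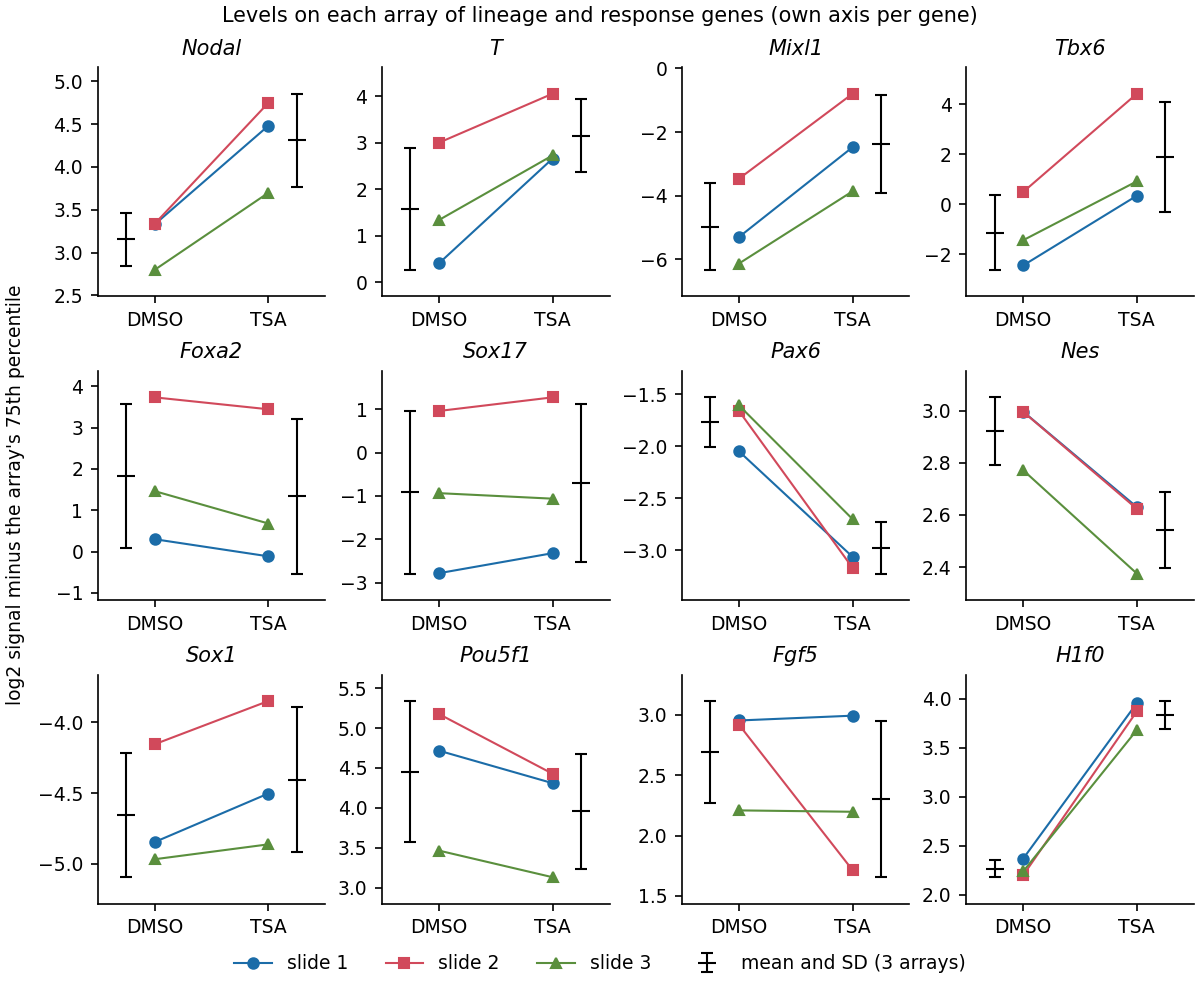
Levels of 12 lineage and response genes (log2 signal minus the array's 75th percentile, own axis per gene) in DMSO and TSA, with arrays of 1 slide joined by a line and bars for the mean and SD of 3 arrays. Nodal, T, Mixl1 and Tbx6 were higher in TSA on each slide without passing the test over all genes, though Mixl1 and Tbx6 passed it with the slide as a block. Foxa2 and Sox17 spread more between slides than between treatments. So did T, whose DMSO levels ran from 0.41 to 3.00. H1f0 rose by 1.57.

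Definitive endoderm genes, the other branch of mesendoderm, were not called. Their 17 tested members had a median of 0.22 (camera adjusted p = 0.976), and 0 rose or fell, over all genes or adjusted over the list alone. Foxa2 gave -0.50 ± 1.16 (adjusted p = 0.876), Sox17 0.22 ± 1.18 (adjusted p = 0.948), Foxa3 1.01 ± 0.36 (adjusted p = 0.327) and Cdx2, an intestinal and posterior gene, 1.46 ± 1.00 (adjusted p = 0.627, and 0.0393 with the slide as a block). Foxa2 was lower in TSA on all 3 slides, without passing with the slide as a block (adjusted p = 0.258). Over the list, 4 members were lower and 6 higher on all 3 slides. The median deviation of the list was 1.67 on TSA replicate 2 and 1.53 on DMSO replicate 2. The 23 tested genes of the Nodal pathway and its direct targets had a median of -0.04, a mean of 0.04 and a test direction downward (adjusted p = 0.487), and 0 rose or fell, over all genes or adjusted over the list alone. Besides Nodal, the co-receptor gene Tdgf1 gave 0.82 ± 0.33 (adjusted p = 0.392), and the feedback inhibitors Lefty1 and Lefty2 gave -0.01 ± 0.54 and 0.73 ± 0.64 (adjusted p = 0.681 for Lefty2). The deviation of this list was 0.51 on TSA replicate 2 and 0.13 on DMSO replicate 2.

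Early neural genes were not called as a group. Their 27 tested members had a median of -0.06 (camera adjusted p = 0.302), and 0 rose or fell over all genes, while 1 rose and 1 fell adjusted over the list alone. Pax6, a transcription factor of neural progenitors, gave -1.21 ± 0.24 (adjusted p = 0.0815, and 0.0569 with the slide as a block) and was lower in TSA on all 3 slides. Nes, an intermediate filament of neural progenitors, gave -0.38 ± 0.20 (adjusted p = 0.534), Sox1, an early neural marker, 0.25 ± 0.35 (adjusted p = 0.786), Sox2 -0.43 ± 0.27 (adjusted p = 0.603) and Zfp521, a driver of neural differentiation, -0.43 ± 0.29 (adjusted p = 0.619). Nes, Sox2 and Zfp521 were also lower in TSA on all 3 slides, without passing with the slide as a block, while Sox1 was higher on all 3. Over the list, 11 members were lower and 7 higher on all 3 slides. Lhx5, a forebrain gene, gave 1.49 ± 0.52 (adjusted p = 0.316, and 0.0424 with the block). The deviation of the list was 0.31 on TSA replicate 2 and 0.29 on DMSO replicate 2. Of 14 tested neural crest genes, a list that was not called (median 0.37, adjusted p = 0.302), 1 rose over all genes, Sox10 (2.15 ± 0.28, adjusted p = 0.0336). Adjusted over the list alone 2 rose, and with the slide as a block 2 rose. Of 33 tested neuronal genes, whose median of 0.01 turned negative with normexp, quantile normalization, median centring and the authors' table (-0.0034 to -0.07), 1 rose and 0 fell over all genes, and 1 rose and 1 fell adjusted over the list alone. Mapt, the microtubule protein tau, rose by 1.83 ± 0.24 (adjusted p = 0.0361), Cplx2, a synaptic protein, gave -1.36 ± 0.23 (adjusted p = 0.0578), and Dcx, a marker of young neurons, gave -1.61 ± 0.63 (adjusted p = 0.382, and 0.0424 with the slide as a block). These 4 genes were chosen after their values were seen.

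Pluripotency genes were not called either. The 17 tested naive genes had a median of 0.37 (adjusted p = 0.327) and the 15 primed epiblast genes -0.22 (adjusted p = 0.327), and 0 members of either list changed, over all genes or adjusted over the list alone. Pou5f1, the core pluripotency factor Oct4, gave -0.50 ± 0.54 (adjusted p = 0.728) and Fgf5, an epiblast marker, -0.39 ± 0.39 (adjusted p = 0.707). Dppa3, a naive and germ cell gene, gave 1.62 ± 0.63 (adjusted p = 0.378) and Tdh, a threonine dehydrogenase of stem cells, 0.83 ± 0.28 (adjusted p = 0.293). On TSA replicate 2 and DMSO replicate 2 the naive list deviated by 0.26 and 0.08, and the primed list by 0.04 and -0.14.

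Genes of the cleavage embryo and of germ cells were higher in TSA as groups and had the lowest adjusted p of the 37 lists by camera, though not with an estimated correlation (adjusted p = 0.693 and 0.878). Of 10 tested genes of the 2-cell-like state, an embryo-like state that rare stem cells enter, 5 rose over all genes and 7 adjusted over the list alone, with a median of 1.89. The 5 were Zscan4c, Usp17la, Tcstv1, Tcstv3 (at least 5.88-fold) and Arg2, an arginase, which rose by 1.97 ± 0.27 (adjusted p = 0.0391) and was chosen after its values were seen. The list was higher by camera (adjusted p = 1.14e-06) and by fry (adjusted p = 0.0289), with medians of 2.46, 1.90 and 1.84 on slides 1, 2 and 3. With an estimated correlation its adjusted p was 0.693. Of 35 tested germline and meiosis genes, 32 had a higher mean in TSA, 3 rose over all genes and 13 rose adjusted over the list alone, with a median of 0.72 (camera adjusted p = 1.14e-05, and 0.878 with an estimated correlation). Tex101, a germ cell surface protein, rose by 1.83 ± 0.24 (adjusted p = 0.0361), Mael, of the piRNA pathway, by 1.78 ± 0.27 (adjusted p = 0.0478) and Stag3, a meiotic cohesin, by 1.64 ± 0.26 (adjusted p = 0.0488). Tdrd9, a piRNA helicase, gave 2.08 ± 0.34 (adjusted p = 0.0536, and 0.0393 with the slide as a block). With the slide as a block, 6 genes of the germline list and 6 of the 2-cell-like list rose. On TSA replicate 2 the germline list deviated by -0.63 and the 2-cell-like list by -0.26, and on DMSO replicate 2 by -0.54 and 0.01; without TSA replicate 2 the germline median was 1.38 and 8 members rose. With normexp background correction both lists stayed called, with smaller medians of 0.54 for the 2-cell-like list and 0.32 for the germline list.

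Genes known to respond to deacetylase inhibitors in other cells were higher as a group. The list sets no expected direction for its genes, so whether each moved as known was not tested. Of 17 tested, 2 rose and 0 fell over all genes, and 5 rose and 1 fell adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.0267, and 0.878 with an estimated correlation). H1f0, a linker histone gene, rose by 1.57 ± 0.19 (2.97-fold, adjusted p = 0.0308) and Mt1, a metallothionein, rose by 1.46 ± 0.21 (adjusted p = 0.0416). Cdkn1a, the cell cycle inhibitor p21, gave 0.66 ± 0.27 (adjusted p = 0.416), the histone gene H2bc4 1.13 ± 0.23 (adjusted p = 0.0860) and Klf6 -0.88 ± 0.21 (adjusted p = 0.141). The deviation of this list was 0.61 on TSA replicate 2 and 0.21 on DMSO replicate 2, and the call ended without TSA replicate 2 (0.27, adjusted p = 0.196) or DMSO replicate 1 (0.42, adjusted p = 0.0522), without slide 2 (adjusted p = 0.139), with array weights (adjusted p = 0.0700), with no filter (adjusted p = 0.0554), or with the mean over a gene's probes (adjusted p = 0.0770). Of the deacetylase genes themselves 10 were tested and 0 changed, over all genes or adjusted over the list alone. Their values ran from -0.45 for Hdac2 (adjusted p = 0.611) to 0.81 for Hdac8 (adjusted p = 0.187), with Hdac3 at 0.07, Hdac4 at -0.36, Hdac5 at 0.26, Hdac6 at 0.36, Hdac7 at 0.09, Hdac9 at -0.38, Hdac10 at -0.05 and Hdac11 at 0.74. The median and mean of this list (0.08 and 0.11) were above 0 while its test, which sets it against the other tested genes and not against 0, pointed downward (adjusted p = 0.976).

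Cholesterol synthesis genes were lower in TSA as a group, with a median of -0.35 over 24 tested genes (camera adjusted p = 1.31e-04, and 0.878 with an estimated correlation). Of these, 20 had a lower mean in TSA, 0 fell over all genes, 1 fell adjusted over the list alone and 1 fell with the slide as a block. The list's medians on slides 1, 2 and 3 were -0.64, -0.04 and -0.22, and the median was -0.19 without TSA replicate 1 (adjusted p = 0.00699). Hmgcs1, an early enzyme of the pathway, gave -0.91 ± 0.35 (adjusted p = 0.380). Mitosis genes had a median of -0.13 over 32 tested, 0 fell, over all genes or adjusted over the list alone, and the list was called downward (adjusted p = 0.0267, and 0.693 with an estimated correlation). The estimated correlation of this list was 0.0040, below the preset 0.01, so that loss does not come from a higher correlation between its genes. Bub1, a checkpoint kinase, gave -0.73 ± 0.42 (adjusted p = 0.568), the list's median on slide 2 was 0.11 and that without TSA replicate 1 was -0.03 (adjusted p = 0.0372), and the call ended without DMSO replicate 1 (-0.11, adjusted p = 0.0522). Genes of the integrated stress response were called downward (adjusted p = 0.0267, and 0.878 with an estimated correlation) with a median of -0.08 over 22 tested, a median that turned to 0.01 with only probes above background on all 6 arrays. The 22 genes parted evenly, 11 with a higher and 11 with a lower mean in TSA, and their median on slide 2 was 0.26. Of these 0 fell over all genes, 2 fell adjusted over the list alone, and 1 fell with the slide as a block. That gene, Nupr1, a stress-induced chromatin protein chosen after its values were seen, gave -1.40 ± 0.50 (adjusted p = 0.327, and 0.0432 with the block). Trib3 gave -1.08 ± 0.21 (adjusted p = 0.0815) and Chac1 -1.14 ± 0.25 (adjusted p = 0.109), both of them targets of the stress factor ATF4. This call ended without DMSO replicate 1 (-0.03, adjusted p = 0.0522), TSA replicate 1 (0.06, adjusted p = 0.148) or DMSO replicate 3 (-0.03, adjusted p = 0.0626), with the authors' table (adjusted p = 0.0501), with array weights (adjusted p = 0.0506), with normexp (adjusted p = 0.0509), and with only probes above background on all 6 arrays (adjusted p = 0.0520). The deviations on TSA replicate 2 and DMSO replicate 2 were 0.74 and 0.23 for cholesterol synthesis, 0.28 and -0.06 for mitosis and 0.37 and -0.19 for the stress response.

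**Figure D3:**
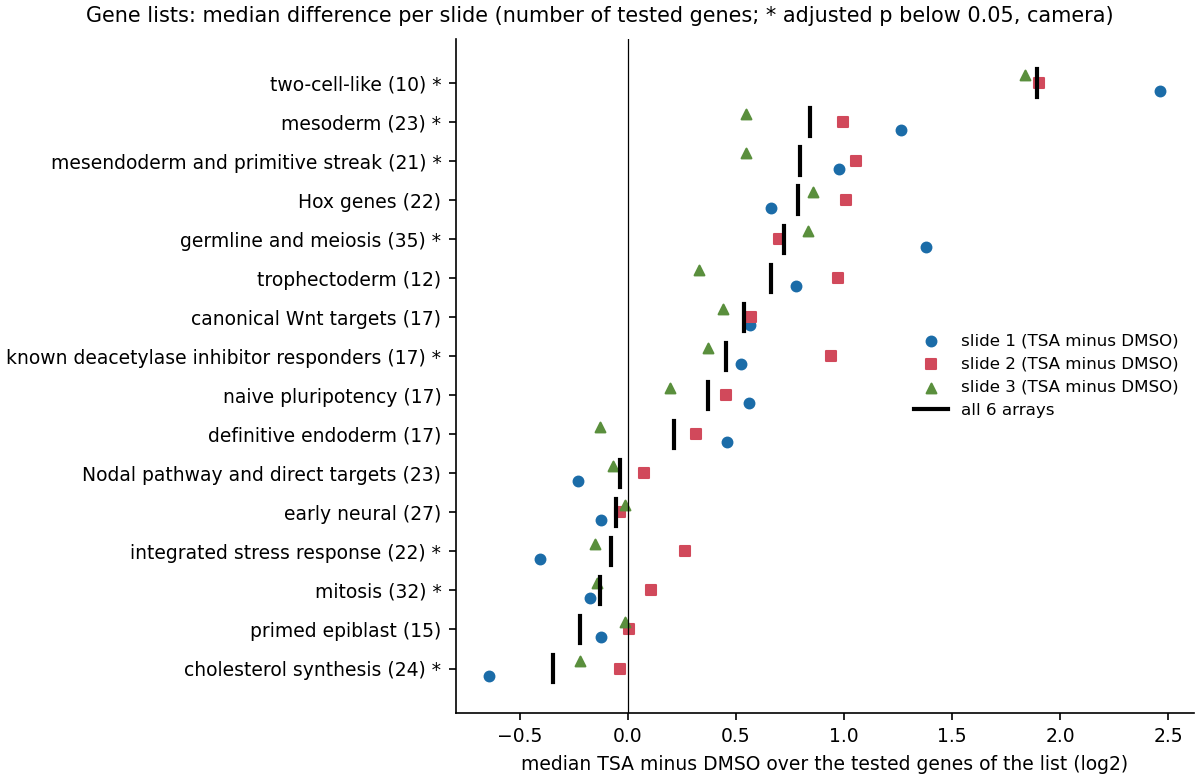
Median TSA minus DMSO difference (log2, x axis) over the tested genes of 16 lists, computed on each slide (coloured points) and from the means of all 6 arrays (black bars), with stars for lists called by camera. The 2-cell-like list reaches 1.89, early neural lies at -0.06, cholesterol synthesis at -0.35, and the integrated stress response lies at -0.08 but turns to 0.01 with only probes above background on all 6 arrays.

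Of the 37 lists, 8 were called, 5 upward and 3 downward, and 29 were not, with medians from -0.22 to 0.79 and a lowest adjusted p of 0.0743. With the slide as a block 11 were called, and the added ones were Hox genes, trophectoderm and canonical Wnt targets. With the block and an estimated correlation none was called, and the lowest adjusted p over the 37 lists was 0.731. An estimated correlation could hardly call a list with 6 arrays, and less so with the block, which takes up further degrees of freedom. Hox genes, which pattern the body axis, had a median of 0.79 over 22 tested (adjusted p = 0.0851, and 1.64e-04 with the block), and Hoxd1 gave 2.30 ± 0.46 (adjusted p = 0.0884, and 0.0424 with the block) and Hoxa7 1.54 ± 0.52 (adjusted p = 0.287, and 0.0375 with the block). Of the Hox genes 0 changed over all genes, 1 rose adjusted over the list alone and 2 rose with the block, and their deviation was 1.62 on TSA replicate 2 and 1.42 on DMSO replicate 2. Trophectoderm genes had a median of 0.66 over 12 tested (adjusted p = 0.0743, and 0.00286 with the block), with Esx1 as the 1 member that rose, over all genes or adjusted over the list alone, 3 that rose with the block, and deviations of 1.02 and 0.66 on the same arrays. Wnt targets had a median of 0.54 over 17 tested (adjusted p = 0.0926, and 0.00205 with the block), with 0 changed, over all genes or adjusted over the list alone, 3 that rose with the block, and deviations of 0.42 and 0.66. Among them Sp5 gave 1.68 ± 0.69 (adjusted p = 0.408, and 0.0349 with the block) and Wnt3a, a streak signal, 2.75 ± 1.17 (adjusted p = 0.430, and 0.0310 with the block). With normexp the median of the Hox list was 0.22 (adjusted p = 0.0801), that of trophectoderm 0.35 (adjusted p = 0.0718) and that of Wnt targets 0.35 (adjusted p = 0.0509). With array weights the median of Wnt targets was 0.15 (adjusted p = 0.0700). In 7 lists the median, the mean and the test differed in sign, the direction of the test being against the other tested genes and not against 0. These were the Nodal pathway, neuronal, imprinted, deacetylase, p53, retinoic acid and ribosomal protein lists, none of them called.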

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

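The alternatives without slide 2, with array weights, with array weights and the slide block together, and with normexp on median spot signals were chosen after seeing the data; the planned normexp alternative on mean signals was not run because the files lack them. Over 24 settings besides the one reported, some for lists only, 31 of 2112 values of the 101 named genes were counted as reversed in sign. Of these, 0 were for genes past the threshold. Of 888 list medians, 51 were counted as reversed, 4 of them for called lists. On each slide alone only reversals of called genes and lists were counted. Sign changes such as definitive endoderm on slide 3 (-0.13) and Lefty1 on slide 2 (0.45) are therefore left out. Settings such as the slide block and fry leave list medians unchanged, so these shares say little about stability. The 26 genes past the threshold that the naming rule takes in kept their direction in every setting that tested them, and all 26 passed with the slide block, with outlier spots kept, with array weights and without TSA replicate 2; 25 passed with an intensity trend, 20 with the authors' table or median centring, 19 with quantile normalization, and 11 with no filter or normexp. The calls of single probes rest on each array but TSA replicate 2: leaving out DMSO replicate 1, 2 or 3 or TSA replicate 1 or 3 ended all of them (0 higher, 0 lower, 0 at 2-fold in limma, with 2006, 2508, 2313, 3327 and 3284 probes at an unadjusted p under 0.05), and the group left with 2 arrays is then assumed to vary like the other. The slide block ended no call of a list or of these genes; what it gained stands beside the genes and lists described. Signal over background limits the dim genes: probes not well above background on at least 3 arrays were not tested, small changes of single genes would mostly be missed with 3 arrays per group, and folds of genes below background in DMSO are lower bounds. Where a call was lost or a sign turned the cause was not tested, except that fewer arrays leave fewer degrees of freedom and no filter means 41174 probes to adjust over.

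Normexp with quantile normalization gave 62 probes higher in TSA and 46 at 2-fold, and list medians of -0.032 for neuronal genes and -0.016 for ribosomal proteins; it lowered those of Hox genes to 0.22, trophectoderm to 0.35, Wnt targets to 0.35 and definitive endoderm to 0.0049. Quantile normalization gave 148 higher and 156 at 2-fold, with -0.0098 for neuronal genes and -0.0043 for ribosomal proteins. Median centring gave 157 and 164, with -0.0034 for neuronal genes. The authors' table gave 142 and 149, with -0.068 for neuronal genes and -0.054 for ribosomal proteins. No filter gave 56 higher, 0 lower (10 in the comparison as reported; 3978 at an unadjusted p under 0.05 in either direction) and 56 at 2-fold, and the mesendoderm list missed the threshold (0.80, adjusted p = 0.0710). Only probes above background on all 6 arrays gave 0.0064 for the integrated stress response. The slide block gave 618 higher, 41 lower and 659 at 2-fold. Without slide 2, limma called 0 higher, 0 lower and 0 at 2-fold, with 5006 probes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0510; the medians were -0.031 for replication-dependent histones, -0.012 for replication licensing and S phase, 0.0029 for p53 targets and apoptosis and -0.091 for ribosomal proteins, and Fgf5 gave 0.014, Hdac9 0.14 and Hdac3 -0.077. Array weights, which were 0.0798 for TSA replicate 2 and 7.0 for TSA replicate 3, gave 2099 higher, 872 lower and 1296 at 2-fold, with -0.11 for neuronal genes, -0.0099 for deacetylase genes, -0.16 for histones, -0.075 for replication licensing, -0.19 for ribosomal proteins, -0.12 for Gsc, -0.38 for Eomes, -0.088 for Sox1, 0.096 for Hdac9, -0.14 for Hdac5 and -0.22 for Hdac3. Weights with the block, whose estimate stopped before it converged, gave 3156 higher, 921 lower, 2177 at 2-fold and 14 lists, with -0.045 for neuronal genes, -0.012 for replication licensing, 0.013 for p53 targets, -0.079 for ribosomal proteins, 0.016 for Hdac9 and -0.13 for Hdac3. An estimated correlation called 0 lists (mesendoderm 0.80, adjusted p = 0.878) and fry called 1 (mesendoderm 0.80, adjusted p = 0.567). The mean over a gene's probes gave 0.012 for corepressor complexes. Slide 1 alone gave 0.56 for naive pluripotency, -0.12 for early neural and -0.23 for the Nodal pathway, and slide 2 alone gave 0.11 for mitosis and 0.26 for the integrated stress response.

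Other lists moved by over 1.5 times when an array was left out. Without TSA replicate 2 the median was 0.32 for Hox genes (adjusted p = 0.563), 0.32 for trophectoderm (0.252) and 0.23 for Wnt targets (0.219), and without DMSO replicate 1 it was 0.33 for Hox genes (0.512), 0.31 for trophectoderm (0.471) and 0.25 for naive pluripotency (0.582). Without TSA replicate 1 it was 1.38 for Hox genes, 1.04 for trophectoderm and 0.68 for the deacetylase inhibitor responders, without DMSO replicate 2 it was 1.36 for Hox genes and 1.38 for mesoderm, and without DMSO replicate 3 it was 0.34 for Wnt targets (0.174). For primed epiblast it ran from -0.14 without TSA replicate 1 to -0.077 without TSA replicate 3 among the arrays that moved it.

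Lists not called as reported gained calls in some settings. Without TSA replicate 2, ribosomal proteins (adjusted p = 0.0156), reference genes (0.0169) and glycolysis and hypoxia (0.010) were called downward, as they were without slide 2 (0.0474, 0.0315 and 0.0109). Array weights called ribosomal proteins (8.60e-04) and reference genes (0.0296) downward and fibroblast markers (0.0294), trophectoderm (0.0117) and Hox genes (0.0229) upward. Weights with the block called glycolysis and hypoxia (0.0156) and reference genes (0.0395) downward and fibroblast markers (0.0485), trophectoderm (0.00227), Hox genes (0.00227) and Wnt targets (5.41e-04) upward. Hox genes were also called with no filter (0.0285), without slide 2 (0.0176), without TSA replicate 1 (7.75e-04) and without DMSO replicate 2 (4.74e-04). Trophectoderm was also called with no filter (0.0223), without TSA replicate 1 (0.00278) and without DMSO replicate 2 (0.0167) or 3 (0.00776). Wnt targets were called without slide 2 (7.36e-04) and without DMSO replicate 2 (0.00233), fibroblast markers without DMSO replicate 3 (0.00365), and histones without TSA replicate 3 (0.0369).

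With each array left out in turn, the probes ran from 0 to 571 higher, 0 to 54 lower and 0 to 582 at 2-fold, the upper ends without TSA replicate 2. The lists called ran from 3 without DMSO replicate 1 to 11 without DMSO replicate 2. The list medians ran from 0.43 to 1.34 for mesendoderm, -0.20 to 0.050 for early neural, -0.24 to 0.066 for the Nodal pathway, -0.42 to 0.77 for definitive endoderm, -0.22 to 0.37 for extraembryonic endoderm, -0.077 to 0.020 for neuronal genes, -0.14 to 0.22 for deacetylase genes, -0.081 to 0.084 for corepressor complexes, -0.10 to 0.59 for histones, -0.052 to 0.31 for replication licensing, -0.056 to 0.012 for p53 targets, -0.22 to 0.74 for retinoic acid response, -0.43 to 0.081 for glycolysis and hypoxia, -0.20 to 0.062 for the integrated stress response, -0.14 to 0.35 for ribosomal proteins and -0.26 to 0.039 for reference genes. The genes ran from -0.54 to 0.44 for Lefty1, -0.32 to 1.45 for Gsc, -0.26 to 0.84 for Eomes, -1.55 to 0.45 for Foxa2, -0.77 to 1.15 for Sox17, -0.026 to 0.50 for Sox1, -0.74 to 0.22 for Hdac9, -0.21 to 0.50 for Hdac5, -0.14 to 0.27 for Hdac7, -0.20 to 0.24 for Hdac3 and -0.29 to 0.15 for Hdac10. All of these except the mesendoderm and stress response lists were uncalled as reported. Leaving out 1 array parts a slide pair, so these ranges also hold level differences between experiments. On slides 1, 2 and 3 Foxa2 differed by -0.41, -0.29 and -0.78 between treatments. Sox17 differed by 0.46, 0.31 and -0.13, and Gsc by 0.99, 0.73 and 0.08.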

Other observations

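The interferon, antigen presentation, blood cell and keratin lists were chosen after seeing the data, and so were the tests of a dimmer array, of the second experiment's stage, of scaling, of TSA replicate 2, of slide position and of weakly expressed genes behind the rises, and of the 2 lineages; the splits, the test of long genes and that of probes near background were planned.

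Genes of immune and blood cells and of the epidermis were also higher in TSA as groups by camera, but each of these 4 lists had an adjusted p of 0.839 with an estimated correlation. Of 31 tested interferon-stimulated genes, which cells switch on against viruses, 30 had a higher mean in TSA and the median was 1.59 on the log2 scale (camera adjusted p = 1.77e-08 over 41 lists, and 0.839 with an estimated correlation), while 1 rose, Oasl1 (1.58 ± 0.23, adjusted p = 0.0425), and 12 rose with the slide as a block. Isg15, a ubiquitin-like modifier, gave 3.16 ± 1.86 (adjusted p = 0.583, and 0.0449 with the block). Of 13 tested antigen presentation genes all 13 had a higher mean (median 1.70, adjusted p = 1.68e-07) and 1 rose, H2-Q8 (1.71 ± 0.26, adjusted p = 0.0441), against 5 with the block. Of 21 tested blood cell genes 7 rose, and 14 with the block (median 1.40 with 2 genes at their lower bound, adjusted p = 1.15e-08), among them Hba-a1, a globin (2.66 ± 0.36, adjusted p = 0.0375), Laptm5 (1.77 ± 0.22, adjusted p = 0.0314) and Cd34, a surface marker of blood progenitors (1.40 ± 0.21, adjusted p = 0.0441). Of 17 tested epidermal and hair keratin genes 5 rose, and 6 with the block (median 0.58, adjusted p = 0.00177), among them Krt79 (2.59 ± 0.22, adjusted p = 0.0208) and Serpinb5 (2.72 ± 0.29, adjusted p = 0.0246), and this call ended without TSA replicate 2 (adjusted p = 0.0594). Of the 17 keratin list genes, 13 had a higher mean in TSA, while Krt1, Krt14, Krt16 and Sprr2a1 gave -0.25, -0.08, -0.22 and -0.13. The preset non-neural ectoderm list, which holds Krt5 and Krt14, was not called (median 0.22, camera adjusted p = 0.390). Since some genes of the 4 lists chosen after seeing the data had been seen to rise, neither the counts nor the adjusted p-values are independent evidence. Adjustment over 41 lists does not correct for that choice.

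Other splits of the 6 arrays into 3 and 3 were fitted in the same way. For probes higher in TSA, lower in TSA and changed at least 2-fold, 1, 1 and 1 of the 10 splits gave as many as the real one (259, 10 and 269, with a highest other of 0 each). For the gene lists 7 of the 10 splits called as many as the real 8, with a highest other of 17. The 4 splits that keep both arrays of slide 1 together called 15 to 17 lists, which points to a structure of the samples that involves slide 1, while the 2 that keep slides 2 and 3 together and part slide 1 called 7 and 9. Among the 4 splits that part all 3 slide pairs, the real one called 8 lists and the others 4, 9 and 2. With 10 splits no share can fall below 0.05.

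TSA replicate 2 stood apart from the other TSA arrays. A dim scan is argued against by the control RNAs. Before scaling, the median of 7 control probes was 12.46 on the log2 scale on TSA replicate 2, against 11.85 to 12.14 on the other arrays. Weak signal of the sample's own RNA stays open. After quantile normalization the highest correlation of TSA replicate 2 with another TSA array was 0.932, against a lowest of 0.984 among the other pairs within a group. Rescaling, however, hardly moves a correlation and keeps the noise of a weak sample. An experiment further along toward mesendoderm may account for the lineage genes, as DMSO replicate 2 deviated there by 1.75; over the 200 genes lowest on TSA replicate 2 its deviation was 0.213 times that of TSA replicate 2, which decides nothing because those genes were picked on that array. A loss of messages from long genes also stays open, with a Spearman rho of -0.342 between its deviation and gene span across 14519 genes, which are not independent replicates. The labels name no difference between the experiments, and no biological explanation other than this stage was tested.

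Rises outnumbered falls, with 96.3% of the changed probes higher in TSA. The choice among the scalings tried is argued against as a cause by a lowest share of 89.9% over 4 others. All 4 bring the arrays to nearly the same centre or distribution, and none uses the control RNAs. An overall shift between the treatments was therefore not tested. Probes near background are argued against by 90.2% among tested probes above their median level (46 rises and 5 falls). TSA replicate 2 is argued against by 91.4% without it, though array weights lowered the share to 70.6%. Slide position and treatment cannot be told apart, because 0 arrays had a position other than that of their group. That weakly expressed genes are opened by TSA is a hypothesis, and 82.2% of the risen probes lay below the median level of the tested probes, where folds have more room to rise than to fall.

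Mesoderm genes were called higher in TSA and definitive endoderm genes were not. The mesoderm call was lost with an estimated correlation (adjusted p = 0.878), without DMSO replicate 1 (0.431), TSA replicate 2 (0.109) or TSA replicate 3 (0.137), and with quantile normalization (0.0569), normexp (0.0551) or no filter (0.0737). It was kept without slide 2 (camera adjusted p = 0.00893). The difference between the list medians was 0.80, 0.68 and 0.67 on slides 1, 2 and 3, and an exact two-sided sign-flip test over the 3 slides gave p = 0.25, the smallest it can give. The second experiment alone is argued against, as the smaller difference of slides 1 and 3 was 0.991 times that of slide 2. A different response of the 2 lineages may exist and stays open with 3 slides.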
